A study of Mus musculus with 6 samples.

How the data were processed

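The study measured poly(A) RNA in 6 libraries of sorted and stimulated splenic Tregs, 3 WT and 3 labelled Bach2-cKO, prepared with an Illumina TruSeq kit from TRIzol-extracted RNA and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, with the genome build mm9. The order of these steps, any filter, the annotation and whether strand was used in counting are not given in the sources used here. The authors deposited FPKM (fragments per kilobase of gene, scaled to the library total), per gene and library, in 1 file per library and in 1 table of the whole series; all 6 files equal their columns in that table. The gene positions in the deposited tables equal those of GENCODE M21, on GRCm38, for 45128 of the 49326 gene identifiers found there (91.5%), which differs from the build in the notes; positions are therefore given as GRCm38. FPKM scales each library to its own total, so a large change in a few abundant genes would shift all others.

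The FPKM values of a gene are whole multiples of what 1 read is worth, and from these steps read totals and whole reads per gene were recovered. With a tolerance of 0.001 reads, all but 3 of the 28530 genes with a value above 0 came out whole, 11800 of them at the annotated exon length and 16727 at another length, and the recovered reads sum to 99.90% to 99.94% of the recovered totals. These reads served for depth, for one alternative test and for one alternative filter. A floor of 3 reads corresponds to between 0.0684 and 0.108 FPKM in a gene of 1 kb. Within each group, replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 10.4 to 23.8 over the genes of a pair, so no library was counted as a copy of another.

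The plan, written before the data were examined, named a negative binomial test on counts as the main test and a linear model on FPKM if no counts were given. Since the deposited values are FPKM, the second is the main test here. Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1), a pseudocount of 1, with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, WT against Bach2-cKO with no covariate, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes and their standard errors are on this log2 scale. In all, 34 gene lists were fixed before the data were examined, and the 32 with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run on the same fit. That setting also takes the degrees of freedom of the test from the libraries, where the preset takes them from the number of genes. Fry was run on the same values and design, without the intensity trend. Figures were drawn with Matplotlib 3.10.9 under Python 3.11.15.

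Genes to be named were fixed by a rule written before the data were examined: 8 genes chosen in advance (Bach2, Foxp3, Il2ra, Il2rb, Bcl6, Cxcr5, Prdm1 and Tcf7); the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM and no overlap between the groups, leaving out predicted genes, pseudogenes and genes without a symbol; and in each list the members with the smallest p, up to 4 for lists of biology and up to 2 for other lists. The rule gave 113 genes, of which those that serve the comparisons are named, and any other gene is said to have been named after its values were seen. Of the 113, 23 overlap another tested gene, 14 of them on the opposite strand.

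The test was checked on simulated reads for 13597 genes with the real libraries' means and totals. Every gene was given the same dispersion, 0.00733, the median over the genes, and genes were drawn independently. The shares recovered apply to this setting. At an adjusted p under 0.05 it recovered 3 of 50 genes changed 1.25-fold, 42 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 50 of 50 changed 4-fold. It also called 14 unchanged genes, 7.25% of all its calls, which include calls in a list planted with a change. That list, planted with a 1.5-fold change, passed camera, and 0 of the other lists did. As genes were drawn independently, this does not show how often camera passes a list whose genes vary together.

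Alternatives fixed in advance were median-ratio scaling, limma-voom on the recovered reads, 2 other filters on low values, a pseudocount of 0.1, the replicate number as a block, leaving out each library, stricter thresholds and the other list tests. A B cell marker score as a covariate, quantile normalization and a robust variance estimate were added after the data were seen. No other column of values was present, and all 6 libraries entered every comparison unless stated.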

Results

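Poly(A) RNA was sequenced from regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain other lymphocytes, taken from spleens of C57BL/6 mice aged 7 weeks. Cells negative for the B cell antigen B220 and positive for CD4 and YFP were sorted, with CD25 as a further marker in the design text of the series. They were then stimulated for 24 hours with plate-bound antibodies against CD3 and CD28. There were 3 libraries from wild-type mice (WT) and 3 labelled Bach2-cKO, by that label a conditional knockout of Bach2. The label does not say which cells lack BACH2. BACH2 is a transcriptional repressor of the BTB and basic leucine zipper family that binds MAF recognition elements. The comparison asked how loss of BACH2 changes gene expression in stimulated Tregs, with interleukin-2 receptor signalling, Treg homeostasis and T follicular regulatory (Tfr) cells named in the title of the series. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The deposited values are FPKM for 49585 genes. Read totals recovered from these values were 43884431, 30893921 and 27697735 for WT replicates 1, 2 and 3, and 27703735, 31976067 and 27777210 for Bach2-cKO replicates 1, 2 and 3. At these depths 1 read in a gene of 1 kb was worth between 0.0228 and 0.0361 FPKM.

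Bach2 itself, on chromosome 4 from 32238804 to 32586108 (GRCm38), had no call between the groups. Its FPKM was 112.0, 111.4 and 99.4 in the WT libraries and 88.9, 104.5 and 120.8 in the libraries labelled Bach2-cKO. The means were 107.6 ± 7.11 and 104.7 ± 16.0 FPKM (SD, n = 3 each), a log2 fold change of -0.048 (SE 0.11, limma adjusted p = 0.812). A value per gene adds up all exons, and the part of the gene that was deleted is not given in the sources used here, so this value does not check the labels. Every direction given for the libraries labelled Bach2-cKO therefore rests on the labels alone. Genes of B cells, which also express Bach2, were abundant in all libraries. Reads of Bach2os, on the opposite strand within the same locus, cannot be told apart from those of Bach2 if strand was not used in counting.

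The libraries labelled Bach2-cKO had 967 genes higher and 1144 genes lower than WT among 13766 genes tested (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). Of these, 188 were at least 2-fold higher and 193 at least 2-fold lower on that scale, which understates the change of weakly expressed genes. The first principal component held 55.0% of the variance and separated the groups, and the libraries correlated at 0.984 to 0.989 within a group and at 0.967 to 0.976 between groups, across genes. The 3 values of one group lay wholly above or below those of the other for 4899 genes, or 35.6% of those tested, where chance gives 10%. The counts fell to 494 higher and 560 lower without WT replicate 1, to 586 and 703 without Bach2-cKO replicate 1, and to 492 and 588 without Bach2-cKO replicate 2, and the lower count to 713 without WT replicate 2. Without Bach2-cKO replicate 3, which lay nearest to WT of its group on the first component (15.1, against 26.2 and 27.9), they were 1224 and 1375. With a B cell marker score per library as a covariate, chosen after the data were seen, 22 genes were higher and 27 lower. Of the 2111 genes called without that covariate, 2105 had the same sign with it, and their log2 fold changes were at a median of 0.966 times, and their standard errors at a median of 2.01 times, the values without it.

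Genes of the IL-2 receptor and its STAT5 pathway moved both ways. Il2ra, the alpha chain that gives the IL-2 receptor its high affinity (chromosome 2, 11642807 to 11693193), rose from 256.3 ± 38.7 to 482.0 ± 22.1 FPKM (SD, n = 3 each; log2 fold change 0.92, SE 0.11, adjusted p = 0.00186). Prdm1, which encodes the repressor BLIMP-1 and which plasma cells also express, rose from 12.7 ± 3.43 to 36.5 ± 2.30 FPKM (log2 fold change 1.48, adjusted p = 0.00154). Socs1, an inhibitor of cytokine signalling, rose by 0.99 on the log2 scale, and Tnfrsf8, which encodes CD30, by 2.32. The beta chain gene Il2rb was at 291.0 ± 33.4 and 288.0 ± 17.9 FPKM (adjusted p = 0.958). The gamma chain gene Il2rg fell by 0.34 on the log2 scale, Stat5b by 0.37 and the kinase gene Jak1 by 0.26. Their limma adjusted p was 0.00881, 0.0288 and 0.0332, and all were named after their values were seen. Igfbp4 fell by 1.27 and the survival gene Bcl2 by 0.68. Of the 29 tested members of the list for this pathway, 10 rose, 6 fell and 13 did not pass, and adjusted over the list alone 14 rose and 7 fell. The 6 that fell became 3 without WT replicate 1, WT replicate 2 or Bach2-cKO replicate 2. The list as a whole was higher than other genes by camera with a preset correlation of 0.01 (median log2 fold change 0.17, adjusted p = 0.0365), with an adjusted p = 0.457 with an estimated correlation. The camera adjusted p became 0.0545 without WT replicate 2, 0.0871 without Bach2-cKO replicate 1 and 0.0561 with quantile normalization.

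Genes of resting Tregs were lower and genes of effector Tregs were higher in the libraries labelled Bach2-cKO. Tcf7, which encodes the transcription factor TCF-1, fell from 200.3 ± 24.3 to 76.5 ± 8.15 FPKM (SD, n = 3 each; log2 fold change -1.37, SE 0.11, adjusted p = 0.000523). The chemokine receptor gene Ccr7 fell by 1.49 on the log2 scale, Lef1, a relative of Tcf7, by 1.12, and the IL-6 receptor gene Il6ra by 1.24. Of 29 tested resting Treg genes, 18 fell and none rose while 11 did not pass, and adjusted over the list alone 18 fell and 2 rose (median log2 fold change -0.70, camera adjusted p = 8.08e-10, adjusted p = 0.173 with an estimated correlation). The receptor for IL-33, Il1rl1, rose from 18.6 ± 3.90 to 87.9 ± 9.60 FPKM (log2 fold change 2.19, adjusted p = 0.000329). Rbpj, the DNA-binding partner of Notch, rose by 1.29 on the log2 scale, and the transcription factor gene Nfil3 by 1.35. Of 40 tested effector Treg genes, 28 rose, 2 fell (Ly6c1 and Ccr6) and 10 did not pass, and adjusted over the list alone 34 rose and 3 fell (median 0.77, camera adjusted p = 1.25e-14, adjusted p = 0.173 with an estimated correlation). Of these 40 genes, 35 also stand in another list, and 19 to 27 rose with 1 library left out. A list of 20 genes shared by T cells, written after the files were opened and before its values were seen, had 8 members that fell and 0 that rose, with a median log2 change of -0.28 (SE 0.067).

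**Figure D1:**
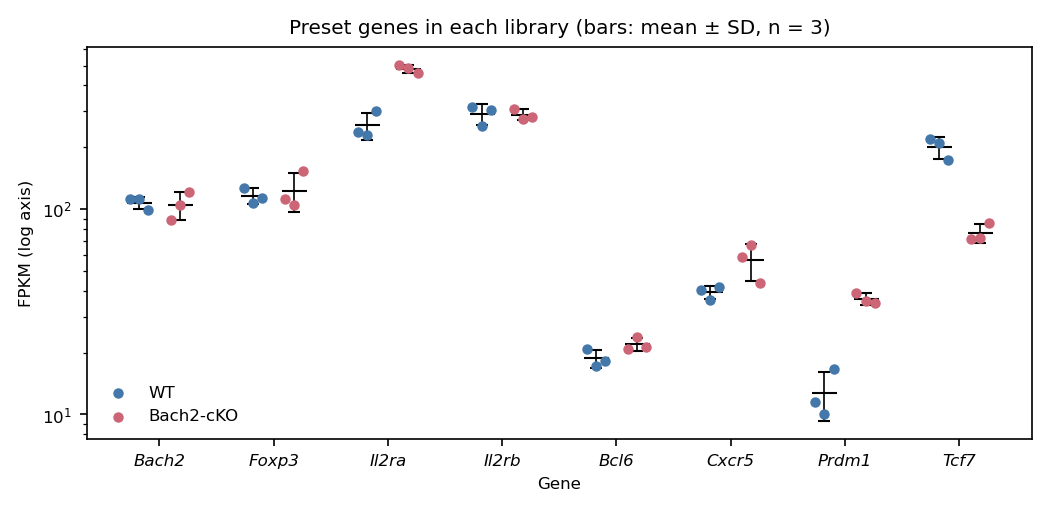
FPKM on a log axis of the 8 genes fixed in advance in each of the 6 libraries; points are libraries, and bars are the mean ± SD of 3 libraries. Il2ra and Prdm1 were higher in all 3 libraries labelled Bach2-cKO than in all 3 WT libraries, Tcf7 was lower in all 3, and Bach2, Foxp3 and Il2rb overlapped between the groups.

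Genes that mark Tregs were divided. Foxp3, the lineage factor of Tregs, was at 116.0 ± 10.1 and 123.2 ± 26.5 FPKM (SD, n = 3 each; log2 fold change 0.068, SE 0.14, adjusted p = 0.786). Rgs1, a regulator of G protein signalling, rose from 45.8 ± 2.19 to 110.0 ± 3.23 FPKM (adjusted p = 0.00011), whereas on the log2 scale Plagl1 fell by 1.80, the orphan receptor gene Gpr83 by 1.75 and Ecm1 by 1.06. Of 28 tested Treg identity genes, 10 rose, 7 fell and 11 did not pass, and adjusted over the list alone 13 rose and 8 fell, with a camera adjusted p = 0.307. With the B cell score as a covariate the median of this list went from 0.029 to 0.27 and its camera adjusted p was 0.0103. Genes of Tfr and T follicular helper cells were divided too. Bcl6, the lineage factor of these cells, was at 18.8 ± 1.91 and 22.0 ± 1.61 FPKM (adjusted p = 0.168), and the follicle homing receptor gene Cxcr5, which B cells also express, at 39.4 ± 2.82 and 56.3 ± 11.7 FPKM (log2 fold change 0.48, SE 0.15, adjusted p = 0.0629). For Cxcr5 the adjusted p was 0.0340 by limma-voom and 0.00518 without Bach2-cKO replicate 3. Cd200 fell by 0.80. Of 33 tested Tfr and Tfh genes, 9 rose, 9 fell and 15 did not pass, and 11 rose and 11 fell adjusted over the list alone. The median of that list was -0.060, its mean 0.0014 and its camera adjusted p = 0.792 on the lower side.

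Among genes of the Th1, Th2 and Th17 lineages and cytotoxic genes, more rose than fell. The type 2 cytokine genes Il13, Il5 and Il4 rose by 3.16, 2.37 and 1.85 on the log2 scale, with Il13 at 3.46 ± 3.07 FPKM in WT and 34.6 ± 11.1 in the libraries labelled Bach2-cKO (SD, n = 3 each; adjusted p = 0.00355). Of 20 tested Th2 genes, 14 rose and 3 fell, or 16 and 3 adjusted over the list alone. The list had a camera adjusted p = 5.71e-08, and an adjusted p = 0.255 with an estimated correlation. Of the Th2 genes 3 fell with all libraries, 2 without Bach2-cKO replicate 3 and 1 with any other library left out. Of 22 tested Th1 genes, 15 rose and none fell (9 and 1 without Bach2-cKO replicate 1), or 17 and 1 adjusted over the list alone. The camera test of the list gave an adjusted p = 3.23e-09, and an adjusted p = 0.173 with an estimated correlation. Those that rose include the chemokine gene Ccl3 by 2.29, Havcr2, which encodes TIM-3, by 1.82 and the IL-12 receptor gene Il12rb2 by 1.36. Of 20 tested Th17 genes, 7 rose and 1 fell (4 rose without WT replicate 1, WT replicate 2 or Bach2-cKO replicate 1), or 7 and 1 adjusted over the list alone. As a list they had a camera adjusted p = 0.000193, and an adjusted p = 0.185 with an estimated correlation. The members with the smallest p besides Cxcr6 were the transcription factor genes Ahr and Maf, at 0.80 and 0.93, which effector T cells of several lineages express. Gzma, which encodes granzyme A, rose from 10.6 ± 2.95 to 108.1 ± 44.7 FPKM (log2 fold change 3.16, SE 0.34, adjusted p = 0.00137). Of 20 tested cytotoxic genes, 10 rose and none fell, or 16 and 2 adjusted over the list alone. Camera on these genes gave an adjusted p = 6.37e-08, and an adjusted p = 0.255 with an estimated correlation. Relative to the mean over libraries, the cytotoxic median was 0.57, 0.42 and 0.028 in Bach2-cKO replicates 1, 2 and 3, and -0.35, -0.45 and -0.34 in the WT libraries. Without Bach2-cKO replicate 3, 17 cytotoxic genes rose, and without WT replicate 1, 6 did. The mean of Cd8a and Cd8b1, both named after their values were seen, was 0.80, 0.49 and -0.062 in Bach2-cKO replicates 1, 2 and 3. Of 8 markers of CD8 T cells 5 rose, 8 adjusted over the list alone (camera adjusted p = 1.51e-05, adjusted p = 0.255 with an estimated correlation), and Cd8b1 went from 21.9 ± 0.463 to 41.2 ± 12.2 FPKM. Of these 8 markers all rose without Bach2-cKO replicate 3, and 1 to 3 rose when one of the other libraries was left out. The CD8 and cytotoxic lists are not separate: 5 of the 8 markers and 11 of 23 cytotoxic genes also stand in another list, and Klrd1 is in both.

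Further lists fixed in advance gave 14 of 37 cytokine and chemokine genes that rose and 2 that fell (9 and 1 without WT replicate 1; 1 fell without WT replicate 2 or Bach2-cKO replicate 2), or 18 and 3 adjusted over the list alone. This list had a camera adjusted p = 1.80e-05, and an adjusted p = 0.178 with an estimated correlation. Ltb, which encodes a lymphotoxin chain, fell by 0.90 on the log2 scale. Of 28 memory-associated genes 15 rose and none fell (10 to 15 rose with 1 library left out), or 17 and 1 adjusted over the list alone. The camera test of the list gave an adjusted p = 5.09e-06, and an adjusted p = 0.274 with an estimated correlation. Cd44, which encodes the hyaluronan receptor, rose by 0.94 and Ly6a by 1.03. Of 36 homing and adhesion genes 13 rose and 6 fell, or 15 and 7 adjusted over the list alone. As a list they had a camera adjusted p = 0.0424, and an adjusted p = 0.487 with an estimated correlation. The camera adjusted p was 0.0785 without WT replicate 2, 0.145 without Bach2-cKO replicate 1 and 0.0639 without Bach2-cKO replicate 3. It was 0.0591 with median-ratio scaling and 0.0596 with quantile normalization. Of 44 genes of T cell receptor activation and AP-1, 9 rose and 6 fell (14 and 11 adjusted over the list alone; camera adjusted p = 0.0774); Dusp5, a phosphatase of ERK, rose by 0.88 while the immediate early gene Nr4a3 fell by 0.55. The 9 that rose became 4 without WT replicate 1, Bach2-cKO replicate 1 or Bach2-cKO replicate 2, and 5 without WT replicate 2. The camera p of this list was 0.0481 without WT replicate 3, 0.0302 without Bach2-cKO replicate 2, 0.0249 with no filter and 0.0381 with the B cell score as a covariate.

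Genes with MAF recognition elements or a role in heme handling included 7 of 25 that rose and 1 that fell, or 8 and 1 adjusted over the list alone. Of these genes 0 fell without WT replicate 1, WT replicate 2 or Bach2-cKO replicate 2. Camera on these genes gave an adjusted p = 3.37e-05, and an adjusted p = 0.336 with an estimated correlation. Srxn1, which encodes sulfiredoxin, rose from 16.0 ± 2.36 to 32.6 ± 1.84 FPKM (SD, n = 3 each; log2 fold change 0.99, adjusted p = 0.00159), and the thioredoxin reductase gene Txnrd1 by 0.66. Of 25 genes of the heat shock and unfolded protein responses 12 rose and none fell (7 rose without WT replicate 1 or Bach2-cKO replicate 2), or 16 and 0 adjusted over the list alone. The list had a camera adjusted p = 1.57e-08, and an adjusted p = 0.173 with an estimated correlation. Asns, which encodes asparagine synthetase, rose by 1.04 and Xbp1, also abundant in plasma cells, by 0.94. Of 30 glycolysis and hypoxia genes 8 rose and 1 fell (5 rose without WT replicate 1, WT replicate 2 or Bach2-cKO replicate 1, and 2 fell without Bach2-cKO replicate 3), or 8 and 1 adjusted over the list alone. The camera test of the list gave an adjusted p = 0.000473, and an adjusted p = 0.487 with an estimated correlation. The angiogenic factor gene Vegfa rose by 0.88 and the kinase gene Pdk1 fell by 0.65. Of 25 cholesterol synthesis genes 10 rose and none fell, or 14 and 0 adjusted over the list alone. As a list they had a camera adjusted p = 5.09e-06, and an adjusted p = 0.336 with an estimated correlation. Of the cholesterol genes 1 rose without WT replicate 1, 2 without WT replicate 2, 3 without Bach2-cKO replicate 1 and 1 without Bach2-cKO replicate 2. The 43 cell cycle genes had a median log2 fold change of 0.43 and 0 passed in limma-trend, with 19 at an unadjusted p under 0.05 and 3 higher by limma-voom; 0 passed adjusted over the list alone. As a list they were higher by camera (adjusted p = 6.37e-08, adjusted p = 0.487 with an estimated correlation). Without Bach2-cKO replicate 3 the median of the cell cycle list was 0.63 and 28 genes passed, all higher. Without WT replicate 3, 2 passed, and without Bach2-cKO replicate 1 the median was 0.29 and 0 passed in limma-trend.

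Of 34 type I interferon response genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.995), with Ifit1 and Usp18 lower by log2 fold changes of -0.84 and -0.79. Without Bach2-cKO replicate 3, 7 interferon genes fell, and 1 rose without WT replicate 1, WT replicate 3 or Bach2-cKO replicate 2. Of 34 apoptosis regulators 3 rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.632), and the death receptor gene Fas fell by 0.77. Without WT replicate 1 or Bach2-cKO replicate 1, 1 of these regulators rose, without Bach2-cKO replicate 3, 6 rose, and without Bach2-cKO replicate 2, 3 fell. Of 40 genes of ribosome biogenesis and MYC targets 1 rose and 1 fell, and 0 passed adjusted over the list alone, with 4 at an unadjusted p under 0.05; limma-voom called 1 higher and 1 lower. The median was -0.014, the mean -0.0061 and the camera test on the higher side (adjusted p = 0.899), which became 0.0363 without Bach2-cKO replicate 3, where 3 of the genes rose. In limma-trend 0 of these genes passed without WT replicate 1, WT replicate 2 or Bach2-cKO replicate 2. Without WT replicate 3 or Bach2-cKO replicate 3, 0 fell, and without Bach2-cKO replicate 1, 0 rose. Of 40 oxidative phosphorylation genes 0 passed in limma-trend and 0 in limma-voom, with 4 at an unadjusted p under 0.05, and 0 adjusted over the list alone (camera adjusted p = 0.394); 3 rose without Bach2-cKO replicate 3. Of 13 mitochondrially encoded genes 0 passed by either tool, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.254, and 0.0358 without WT replicate 3). Of 34 ribosomal protein genes 1 fell (0 adjusted over the list alone, 8 at an unadjusted p under 0.05, 2 lower by limma-voom); the call was lost with any library left out. Their median was -0.16 (camera adjusted p = 0.000382, adjusted p = 0.644 with an estimated correlation), and -0.10 without Bach2-cKO replicate 3. In all, 21 of 32 lists passed camera with the preset correlation, 19 higher and 2 lower. Many lists share members, so these are not 21 separate results. Of 24 Th2 genes 20 also stand in another list, as do 16 of 22 Th1 genes and 27 of 43 cytokine and chemokine genes, but 0 of 43 cell cycle genes. With an estimated correlation 0 passed, with 7 at an unadjusted p under 0.05, and 13 passed fry, which asks only whether a list's genes move on balance one way.

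**Figure D2:**
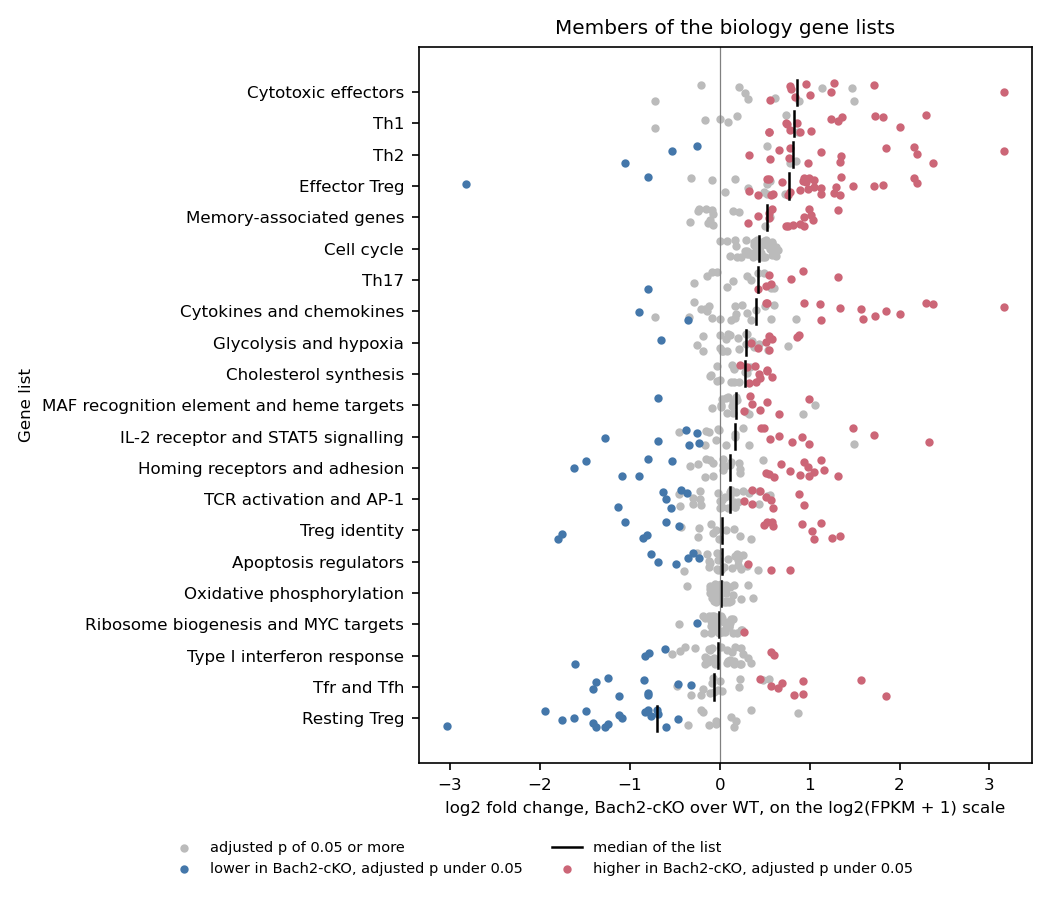
Log2 fold change (Bach2-cKO over WT, on the log2(FPKM + 1) scale) of each tested member of the biology lists, 1 row per list ordered by its median (black line); coloured points passed an adjusted p of 0.05. The resting Treg list lies lowest, with a median of -0.70, and the cytotoxic list highest, with a median of 0.86.

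The largest rises among genes with a mean of at least 5 FPKM and no overlap between the groups were in genes of several kinds. The immunoglobulin variable genes Igkv12-89, Ighv1-55 and Ighv2-9 rose by 3.76, 2.61 and 2.23 on the log2 scale; they belong to families of near-identical copies, so the split of reads among members is uncertain, and Igkv12-89 was at 16.6 ± 11.8 and 240.2 ± 131.4 FPKM (SD, n = 3 each). With the B cell score as a covariate the log2 fold changes were 2.01 (SE 0.91, adjusted p = 0.393) for Igkv12-89, 1.15 (SE 0.63, adjusted p = 0.457) for Ighv1-55 and 2.67 (SE 0.33, adjusted p = 0.0452) for Ighv2-9. The others besides Gzma, Il13, Tnfrsf8 and Ccl3 were the inhibitory receptor gene Lilrb4a, which rose from 10.7 ± 2.13 to 73.0 ± 4.04 FPKM (log2 fold change 2.68, SE 0.13, adjusted p = 0.00011), Cd300lf by 2.40 and Nradd by 2.21. The largest falls were in Gsta4, a glutathione transferase (chromosome 9, 78182774 to 78209349), from 25.3, 26.7 and 28.3 FPKM in the WT libraries to 1.09, 0.691 and 1.26 in the others (log2 fold change -3.79, SE 0.13, adjusted p = 3.50e-05), and in Gata1, the erythroid transcription factor (chromosome X, 7959260 to 7978071), from 20.2 ± 1.74 to 1.46 ± 0.555 FPKM (log2 fold change -3.13, adjusted p = 0.000167). Arhgap20 fell by 3.04, Ly6c1 by 2.83, Nsg2 by 2.77, the bacterial sensor gene Nod1 by 2.35, Prg4 by 2.27, the synaptic vesicle gene Syp by 2.25, the ciliary transport gene Ift80 by 2.23 and Ifit1bl1 by 2.20. Ift80 and Prg4 overlap other expressed genes, and Ly6c1 has close paralogs.

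Markers of other cells moved with the groups, beside the gene groups above. B cell genes were abundant in all 6 libraries although B220-positive cells were excluded by the sort: Pax5, named after its values were seen, was at 181.5 ± 17.3 FPKM in WT and at 284.6 ± 32.1 in the libraries labelled Bach2-cKO (SD, n = 3 each). Of 21 B cell genes 11 rose and none fell (6 rose without WT replicate 1 and 7 without WT replicate 3), or 12 and 0 adjusted over the list alone. Camera on these genes gave an adjusted p = 6.37e-08, and an adjusted p = 0.336 with an estimated correlation. Cd74 and H2-Ab1, of antigen presentation, rose by 1.01 and 1.08 on the log2 scale. Immunoglobulin genes took 0.370%, 0.448% and 0.370% of reads in the WT libraries and 0.635%, 0.791% and 0.625% in the others. Of 10 plasma cell genes 5 rose, or 5 adjusted over the list alone. That list had a camera adjusted p = 0.000998, and an adjusted p = 0.262 with an estimated correlation. Of 20 listed monocyte and macrophage genes only 9 reached the filter. Of these 9, 4 rose (2 without WT replicate 1, WT replicate 3 or Bach2-cKO replicate 1, and 1 without Bach2-cKO replicate 2), or 4 adjusted over the list alone. The camera test of the list gave an adjusted p = 0.00126, and an adjusted p = 0.255 with an estimated correlation. Of 11 dendritic cell genes 5 rose and 1 fell, or 7 and 1 adjusted over the list alone. Without WT replicate 2, 3 rose, and with 1 library left out a fall was kept only without Bach2-cKO replicate 1. The dendritic cell list had a camera adjusted p = 0.000702, and an adjusted p = 0.173 with an estimated correlation. Of its 14 genes, 6 also stand in another list. Its members with the smallest p, Klrd1 and H2-Ab1, are also in the lists of CD8 T cells and of B cells. With the B cell score as a covariate the monocyte list had a median of 0.33, against 0.65 without it, and a camera adjusted p = 0.170. The score is the median of the B cell list itself, so that list cannot be tested with it. Of 8 genes of conventional CD4 T cells 3 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of -0.097, a mean of 0.011 and a camera adjusted p = 0.792 on the higher side. Of 5 neutrophil genes 0 passed in limma-trend or over the list alone, with 1 at an unadjusted p under 0.05 and 1 by limma-voom (camera adjusted p = 0.0774). That p was 9.09e-06 without Bach2-cKO replicate 1, 0.0343 with the replicate block and 0.00915 with no filter; 3 of these genes rose without Bach2-cKO replicate 1 and 1 without WT replicate 3. Of 7 erythroid and platelet genes only Itga2b passed, lower by a log2 fold change of -0.93 (1 adjusted over the list alone; camera adjusted p = 0.523 on the higher side, and 0.0119 without Bach2-cKO replicate 1, where 1 gene also rose). The lists of NK cells and of stromal cells, with 4 and 3 tested genes, were too short for camera; in the first Gzma rose, and in the second Pecam1 and Fbln1 fell, by 0.73 and 0.78, of which 1 passed without WT replicate 1, WT replicate 3, Bach2-cKO replicate 1 or Bach2-cKO replicate 2.

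**Figure D3:**
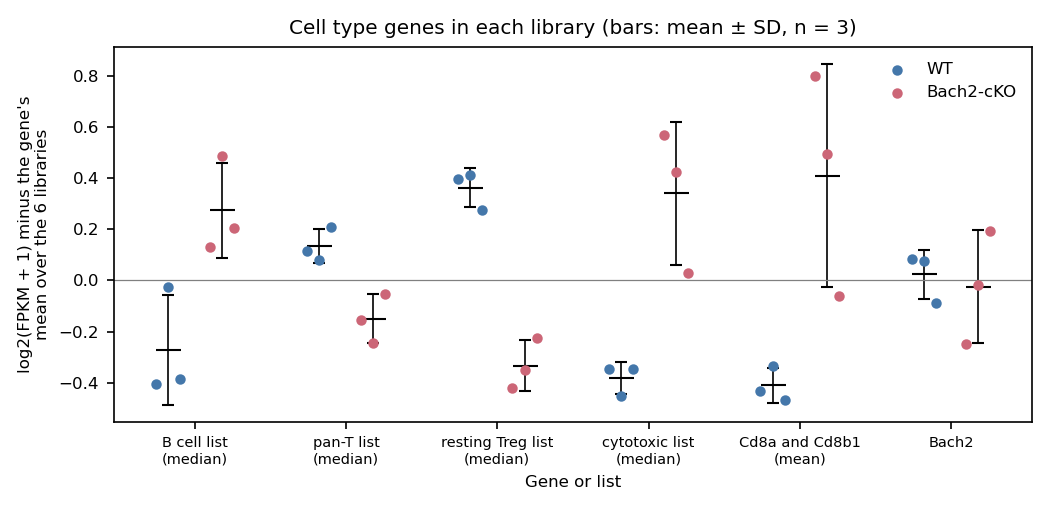
Median or mean over a list of log2(FPKM + 1) minus each gene's mean over the 6 libraries, per library, with bars for the mean ± SD of 3 libraries. The B cell medians lie between -0.41 and -0.024 in WT and between 0.13 and 0.49 in the libraries labelled Bach2-cKO, whereas Bach2 overlaps between the groups.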

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

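The alternatives were fixed before the data were examined, except the B cell score covariate, quantile normalization and the robust variance estimate, which were added after the data were seen. Under median-ratio scaling, limma-voom on the recovered reads, the filter of 1 CPM, a pseudocount of 0.1, quantile normalization and the robust estimate, the counts of higher genes lay between 942 and 1166 and those of lower genes between 1035 and 1351, near 967 and 1144. No scaling moved the median of all genes by more than 0.02 on the log2 scale. With no filter beyond a value above 0, 28530 genes were tested, and 501 were higher and 681 lower. An adjusted p under 0.01 left 341 and 454, and a 2-fold change 188 and 193. The B cell score as a covariate left 22 and 27. Of the 112 named genes other than Bach2, 75 lost their call. The 112 include genes without a call in the main test, such as Foxp3 and Bcl6, which had none to lose. The score correlates with the groups, so standard errors rose. It also reduced the size of the log2 fold changes of several named genes by over 1.5 times. Among them were Nr4a3, Txnrd1, Vegfa and Apoe, at -0.30, 0.43, 0.48 and 0.33 with the score, and Igkv12-89 and Ighv1-55, at 2.01 and 1.15. Leaving out one library gave 492 to 1224 higher and 560 to 1375 lower. With the replicate block 625 were higher and 657 lower. The deviations of same-numbered libraries correlated at -0.0526, 0.00578 and -0.215 across genes, and those of other pairs at -0.134 to 0.177. With 3 libraries per group these values cannot show whether the numbers pair the samples, which the labels do not say. The block ended the calls of 7 named genes. The edgeR quasi-likelihood test, the negative binomial test planned for deposited counts, was not run. On the recovered reads the test was limma-voom. Library size alone is already the scaling of FPKM.

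Of the 32 lists, 21 passed camera, and 19 to 23 did under the other settings of the gene fit that tested the same 32. With no filter 24 of 34 passed, and with the CPM filter 22 of 33. Of the 32, 0 passed with an estimated correlation (7 at an unadjusted p under 0.05) and 13 by fry. Both camera runs used the same fit but differed in the correlation and in the degrees of freedom. With an estimated correlation these come from the libraries and are far fewer. The estimates of the correlation ran from -0.052 (dendritic cells) to 0.88 (cell cycle), against the preset 0.01. The dendritic cell list, estimated below the preset, still went from an unadjusted camera p of 0.000373 to 0.0202. A correlation below the preset cannot raise p, so in this list the rise comes from the fewer degrees of freedom. In the other lists the parts of the correlation and of the degrees of freedom were not separated. The cause of the difference from fry was not tested. The log2 fold change of Bach2 ran from -0.16 to 0.064 when one library was left out and did not pass in any setting. The B cell list, called in the main test, had a median of -0.048 with the B cell score, which is that list's own median. The other changes of direction were in genes and lists without a call in the main test: Foxp3 from -0.10 to 0.18 and Il2rb from -0.11 to 0.051 with one library left out, Il2rb 0.012 with median-ratio scaling and 0.33 with the B cell score, and Slc4a1 -1.21 with that score. List medians, where the camera direction turned, were 0.053 (Tfr and Tfh), -0.015 (oxidative phosphorylation), -0.061 (ribosome biogenesis) and -1.21 (erythroid, adjusted p = 0.0147, which alone passed) with the B cell score, and -0.016 with quantile normalization for ribosome biogenesis. For type I interferon genes they were 0.011 with no filter, -0.020 with the CPM filter, -0.020 with a pseudocount of 0.1 and -0.020 with the replicate block. By fry they were -0.014 (ribosome biogenesis), 0.027 (apoptosis), -0.097 (conventional CD4) and 0.78 (erythroid). With one library left out the medians ran from -0.088 to 0.012 (Tfr and Tfh), -0.020 to 0.068 (oxidative phosphorylation), -0.069 to 0.079 (ribosome biogenesis) and -0.073 to 0.073 (interferon). The cause of these was not tested. With these depths and 3 libraries per group, 42 of 50 genes simulated at 1.5-fold were recovered, and 3 of 50 at the smaller change in the simulation. The simulation gave all genes the same dispersion, so recovery of genes with a larger spread was not measured.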

Other observations

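The pan-T comparison and the counts over other splits were fixed before their results were seen; the tests on B cell genes, on Bach2 and on CD8 T cells were chosen only after the result was seen. Further members of the lists, named after their values were seen, include the transcription factor gene Epas1, which rose from 1.85 ± 0.553 to 12.2 ± 4.35 FPKM (SD, n = 3 each), the ectoenzyme gene Entpd1 from 35.5 ± 3.43 to 73.1 ± 5.67, Fgl2 from 25.8 ± 3.85 to 63.2 ± 4.54, and Tigit, an inhibitory receptor gene, from 185.7 ± 28.8 to 384.6 ± 59.1. The neuropilin gene Nrp1 fell from 27.9 ± 2.97 to 15.0 ± 2.17 FPKM, and Id3, an inhibitor of E proteins, from 71.4 ± 17.4 to 26.2 ± 6.53. Themis, a T cell signalling gene, rose by 1.11 on the log2 scale, and Tox2 from 6.55 ± 0.259 to 13.3 ± 1.26 FPKM. Among genes shared by T cells, Prkcq, named after its values were seen, fell from 67.3 ± 0.849 to 34.9 ± 1.94 FPKM.

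The real split of the 6 libraries gave 967 genes higher and 1144 lower, and 1 of the 10 splits into 3 and 3, the real one, gave as many in either direction. The highest count in the other 9 splits was 0 by limma-trend and 0 by limma-voom, with 187 to 1374 genes at an unadjusted p under 0.05 against 4241 in the real split. With 10 splits no share under 0.1 can be had, so these counts are too few to test chance.

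Of 21 B cell genes 11 rose in the libraries labelled Bach2-cKO, or 6 without WT replicate 1, and the list had an adjusted p = 0.336 with an estimated correlation. Ighm, Igkc and Spib are named here after their values were seen, with Ighm at 1326 ± 187.0 and 2241 ± 274.0 FPKM and Igkc at 809.8 ± 90.6 and 1532 ± 312.7, although the sort excluded B220-positive cells. A larger share of the same B cells is a candidate explanation. It needs every B cell gene to rise by one factor, and in limma 0 of 21 genes differed from the list median in a way that changed between the groups, adjusted over the list alone. This is a narrow outcome, since 9 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0532, shared by 4 genes, with Spib at -0.45 and Igkc at 0.36 relative to the median; unequal rises, as in B cells of another state, stay open. All 21 genes passed the filter and 2 also stand in another list; a difference in B cells brought by the genotype was not tested.

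Bach2 had no call between the groups (log2 fold change -0.048, SE 0.11, and -0.16 to 0.064 with one library left out), which does not show that its level was equal. If all Bach2 reads came from B cells, Bach2 would have followed the B cell list, but its change differed from that of the list median by -0.59 (SE 0.18). Over the 21 B cell genes the same difference had an SD of 0.33 and reached -0.49. Bach2 thus lay below every B cell gene of the list. It did not pass the limit set for this test from its SE and that SD together, so this explanation stays open. An exchange of one library between the groups is argued against, as 0 of the 6 libraries correlated best with a library of the other group. A fall of Bach2 in Tregs offset by reads from more B cells may still hold and cannot be told apart from an unchanged level, since these values are neither per exon nor per cell type.

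In the libraries labelled Bach2-cKO 18 of 29 resting Treg genes fell and 10 of 20 cytotoxic genes rose, with an adjusted p = 0.173 and 0.255 for the lists with an estimated correlation. Dilution of T cell RNA by B cell RNA may lower T cell genes, but the median of the resting Treg list fell beyond that of 20 pan-T genes, a difference of -0.41 (SE 0.094), which argues against dilution as the whole cause. A larger share of CD8 T cells could raise cytotoxic genes: in limma 2 of the 20 tested cytotoxic genes, Gzma and Gzmb, rose beyond the mean of Cd8a and Cd8b1, by 2.34 and 0.90, adjusted over the list alone. Lamp1 and Ccl5 lay below that mean by 1.03 and 1.54, and 16 passed in neither direction. These 4 differ from what a larger share of the same cells gives, but other cells also express Lamp1 and Ccl5, and the rest leave this explanation open although the sort took CD4-positive cells. Gzmb, Cd8a, Cd8b1, Lamp1 and Ccl5 are named after their values were seen. Cd8a was at 19.9 ± 1.62 and 36.4 ± 10.7 FPKM. Expression of these genes by Tregs of the labelled genotype was not tested apart from other cells.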
